A study of Hordeum vulgare with 18 samples.

How the data were processed

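RNA of 18 highland barley samples was measured, leaf and root at 3 rates of organic fertilizer nitrogen with 3 libraries per group. Per the labels, RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra RNA kit. The raw read counts per gene were used as deposited by the authors, whose notes name CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 without saying what each did. The notes also name the mouse builds GRCm38 and mm10, while all 68630 loci of the table lie on scaffolds of a barley assembly, so positions here are those of the scaffolds. How reads on either strand or at several places were counted is not given in the sources used here. The table also lists the gene length (other values, in bases, per the file headers), which was not used. Genes were named by the descriptions in the table, which are automatic annotations. Of the loci, 5073 were assembled from the reads and hold 8.37 to 10.3% of the counts of a library, and these are named here by annotation and position.

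Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with TMM scaling factors and 2-sided p adjusted by Benjamini-Hochberg over all genes tested, at a threshold of 0.05. Genes of low counts were removed with filterByExpr (minimum count 10, minimum total 15). The 9 libraries of a tissue were fitted together with a mean per group, which left 6 residual degrees of freedom and 20032 genes in leaf and 21895 in root. The biological coefficient of variation was 45.8% in leaf, 27.7% in root and 38.7% over both. The difference between the responses of root and leaf, and leaf against root at 0%, were tested on all 18 libraries (24046 genes, 12 residual degrees of freedom). The SE of a log2 change was computed from the change and its F value. The p-values measure only the spread between these samples, since nothing in the sources says that the libraries of a group came from separate plants or pots. No block was used, since the labels do not pair replicates. Residuals of same-number libraries correlated at -0.16 to 0.16.

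A list of 35 sets of genes, each found by words in the descriptions, was fixed together with the tests, the comparisons, the rule for naming genes and most alternatives before the data were examined. Each set with at least 5 tested genes was tested with camera of limma 3.58.1 at a preset correlation of 0.01, on log2 CPM with a prior count of 2. None of the calls held with an estimated correlation. The words of the clock set also matched efflux carriers, 123 of its 145 loci, and 1804 loci of the ribosomal set had only the description of protein S5-1. Both sets were therefore also tested without these loci, a choice made after seeing the data.

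Genes were named by rule. For each comparison with the control these were the 10 called members of smallest adjusted p of the nitrogen sets (nitrate transport, the NPF family, ammonium transport, nitrate reduction and ammonium assimilation, amino acid and oligopeptide transport, urea and ureide metabolism). To these came the 6 largest rises and 6 largest falls among called genes with an informative description, complete separation of the replicates and at least 5 CPM in the higher group. For each other set that passed, the 2 called members of smallest adjusted p in its direction were added. For 100% against 40% these numbers were 4, 3, 3 and 1. In each tissue the most abundant member of each nitrogen set was named, called or not. Another 17 genes were chosen after their values were seen and are marked so in the text.

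A count of 3 per library was taken as the floor for genes with no count in a group, and ratios against 1 to 3 counts are given with an exact binomial interval of 95% confidence. Intervals and floors cover counting error only. The tools were tested on simulated counts with the spread of these data and 200 changed genes. At a fold of 2, 4 and 8 edgeR recovered 1.33, 42.7 and 72% of them in leaf, with 2.67 false calls on average. In root it recovered 21.3, 72.7 and 92.7%, with 5.67 false calls. DESeq2 1.42.0 recovered 15.3, 68.7 and 90.7% in leaf with 57.7 false calls, and 46.7, 87.3 and 96% in root with 40.3. With no gene changed edgeR called 0 genes in leaf and 0.333 in root on average.

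The alternatives tried were a minimum log2 change of 1, RLE factors, no filter, a minimum of 5 CPM in 3 libraries, a replicate block, scaling without the 20 most abundant genes, DESeq2, the 6 compared libraries alone, all 18 libraries in 1 fit, and leaving out each library in turn. For the sets, fry and an estimated correlation were also tried. Library size alone, limma voom with estimated sample weights, and leaving out control leaf 2 in comparisons beyond those planned were chosen after seeing the data. An alternative unit was not run, since the table holds counts only.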

Results

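RNA was sequenced from highland barley, a hulless barley of high altitudes, grown in pots and sampled at flowering. Organic fertilizer replaced 0, 40 or 100% of the nitrogen given as chemical fertilizer, with total nitrogen, phosphorus and potassium kept equal between the rates. The 0% pots, called the controls here, received 357 mg of urea, 1545 mg of superphosphate and 140 mg of potassium sulfate. The 40% pots received 215 mg of urea, 1443 mg of superphosphate, 122 mg of potassium sulfate and 1117 mg of organic fertilizer. The 100% pots received no urea, 1289 mg of superphosphate, 96 mg of potassium sulfate and 2793 mg of organic fertilizer. Leaf and root at the 3 rates gave 6 groups of 3 libraries, 18 in all. The sample titles name leaf and root, while the study's design speaks of the parts above and below ground.

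The count table held 68630 loci, of which 32529 had a count in at least 1 library. Total counts were 16.5 to 19 M per leaf library and 13 to 16.9 M per root library, and 19180 to 26584 loci per library had a count. The 10 most abundant genes took 8.23 to 12% of the counts of a leaf library and 3.19 to 4.1% of those of a root library. A count of 3 equalled 0.158 to 0.231 counts per 1e6 counts of the library (CPM). Levels are CPM of the library total, as mean ± SD of 3 libraries. Changes are log2 fold changes of the scaled counts ± SE from edgeR, with p adjusted over all genes tested. A set-adjusted p is that of a list of genes tested as a whole, adjusted over the lists. In each gene named as risen or fallen, all 3 libraries of one group lay above the other 3 (10% by chance per gene). Genes only counted need not do so.

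**Figure D1:**
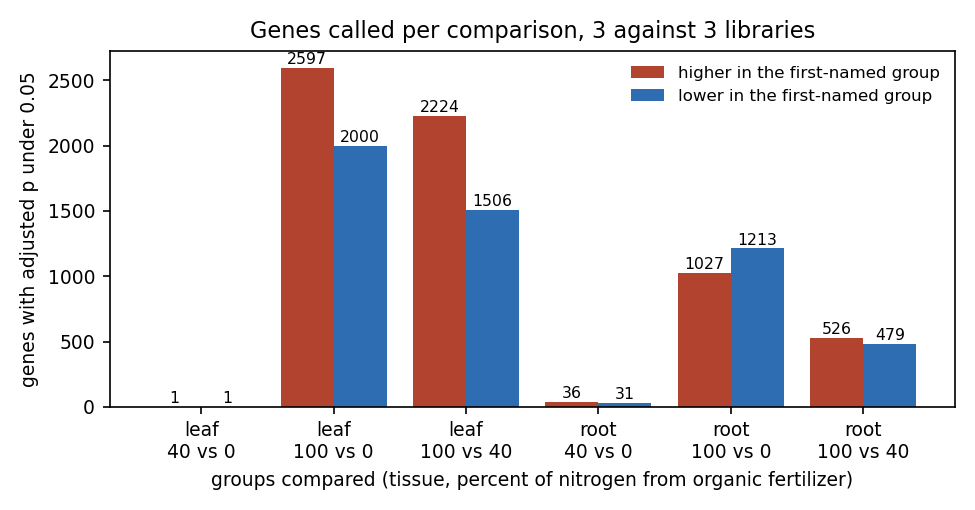
Number of genes called higher (red bars) and lower (blue bars) in the first-named group at an adjusted p under 0.05, for each comparison of 2 fertilizer rates in leaf and in root, with 3 libraries per group. Leaves gave 2 calls between 40% and the control and 4597 between 100% and the control, and roots gave 67 and 2240.

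Leaves at 100% organic nitrogen were compared with control leaves to ask which genes differed. Their hours of harvest may also differ. Nitrate reductase D1007_31007, the enzyme that reduces nitrate to nitrite (scaffold SDOW01000340.1, 954247 to 959135, plus strand), rose from 3.21 ± 2.37 to 453 ± 234 CPM. Ferredoxin-nitrite reductase D1007_08673, the next step of nitrate assimilation (SDOW01000066.1, 3678579 to 3681627, minus strand), rose from 153 ± 30 to 716 ± 386 CPM. PsbS D1007_48858, 5'-adenylylsulfate reductase 1 D1007_25844 and heat stress transcription factor A-2d D1007_16146 rose along with them. Of 20032 genes tested, 4597 (22.9%) were called, 2597 higher and 2000 lower, and 7427 had an unadjusted p below 0.05. The call count was 2756 without control leaf 1 and 2388 without control leaf 3. Scaling by library size alone shifted the median log2 change of all genes by -0.25 and made 37.2% of the calls higher, against 56.5% with the scaling used, and all 18 libraries in 1 fit made it 49.6%.

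Among the nitrogen genes, nitrate reductase D1007_31007 rose by a log2 change of 7.40 ± 0.84 (adjusted p = 0.00066) and ferredoxin-nitrite reductase D1007_08673 by 2.48 ± 0.39 (adjusted p = 0.0028). Chloroplast glutamine synthetase D1007_32310, which joins ammonium to glutamate, was the most abundant member of the assimilation list and rose from 641 ± 153 to 1400 ± 214 CPM (1.38 ± 0.27, adjusted p = 0.0067). The other glutamine synthetase D1007_38808, chosen after its values were seen, went the opposite way, from 1600 ± 856 to 300 ± 109 CPM (-2.16 ± 0.46, adjusted p = 0.01). Of 18 tested genes of nitrate reduction and ammonium assimilation, 4 rose and 2 fell, which was also the count adjusted over the list alone. The list as a set had an adjusted p of 0.596, with a median log2 change of -0.02 and a mean of 0.36, so its middle and its mean differed in sign.

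Transporters moved in both directions. The NRT1/PTR family (NPF), carriers of nitrate and peptides, had 13 members higher and 15 lower of 70 tested (14 and 16 adjusted over the list alone, set-adjusted p = 0.676). The nitrate transport list, most of whose loci (112 of 131 in the table) are also in the NPF list, had 11 higher and 11 lower of 57 (11 and 13 adjusted over the list alone, set-adjusted p = 0.767). NPF8.3 D1007_22593 rose by 2.96 ± 0.40, NPF4.6 D1007_29299 by 2.95 ± 0.39 and NPF6.4 D1007_17999, the most abundant member in leaves, by 0.97 ± 0.25 from 340 ± 77.8 to 561 ± 98.7 CPM. NPF7.3 D1007_00549 had 1 count over the control leaves and 816 over the 100% leaves, a ratio of 858 with a 95% counting interval from 153 upward, or 493 without 100% leaf 1. Another gene annotated NPF8.3, D1007_24918, fell from 90.2 ± 15.7 to 10.8 ± 2 CPM, and NPF5.1 D1007_28888 fell from 75.9 ± 29.5 to 10.7 ± 1.07 CPM. Of 3 ammonium transporters tested, 1 rose and 1 fell, and ammonium transporter AMT2;1 D1007_10500 was the most abundant, at 39.7 ± 19.4 CPM in control leaves and 6.35 ± 4.82 at 100% (-2.38 ± 0.61, adjusted p = 0.021). The NPF6.4 call (adjusted p = 0.022, alternatives 0.00092 to 0.077) was lost without control leaf 2 (0.055), control leaf 3 (0.077) or 100% leaf 1 (0.061). That of AMT2;1 (alternatives 0.001 to 0.088) was lost without control leaf 3 (0.088) or 100% leaf 2 (0.061).

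Genes of organic nitrogen moved in both directions, and neither of their lists passed as a set. In the urea and ureide list 1 of 16 tested genes rose and 5 fell (3 and 6 adjusted over the list alone, set-adjusted p = 0.48). Uricase D1007_27011, which oxidises uric acid in purine breakdown, fell from 232 ± 86.8 to 38.1 ± 3.57 CPM (-2.35 ± 0.29, adjusted p = 0.00095). Urease accessory protein F, which helps to load nickel into urease (locus SDOW01000586.1, 1406454 to 1411983, plus strand), fell from 30.9 ± 2.96 to 8.29 ± 1.57 CPM. The most abundant member, allantoate deiminase D1007_57662, was at 249 ± 142 and 764 ± 564 CPM (adjusted p = 0.052). Of 89 amino acid and oligopeptide transporters 8 rose and 12 fell, the same counts adjusted over the list alone (set-adjusted p = 0.767). Vacuolar cationic amino acid transporter 2 D1007_39707 fell from 352 ± 112 to 120 ± 15.6 CPM, whereas YPQ1 D1007_00095, a vacuolar amino acid carrier, rose from 11.4 ± 2.93 to 42 ± 16 CPM. The urea transporter DUR3 D1007_41289 fell by 2.00 on the log2 scale (SE 0.59, adjusted p = 0.037) and oligopeptide transporter 7 D1007_44798 fell by 2.49 (SE 0.49, adjusted p = 0.0073), both chosen after their values were seen. The DUR3 call was lost without control leaf 1 (0.1), control leaf 3 (0.12), 100% leaf 2 (0.067) or 100% leaf 3 (0.076), and its alternatives gave 0.0048 to 0.12.

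**Figure D2:**
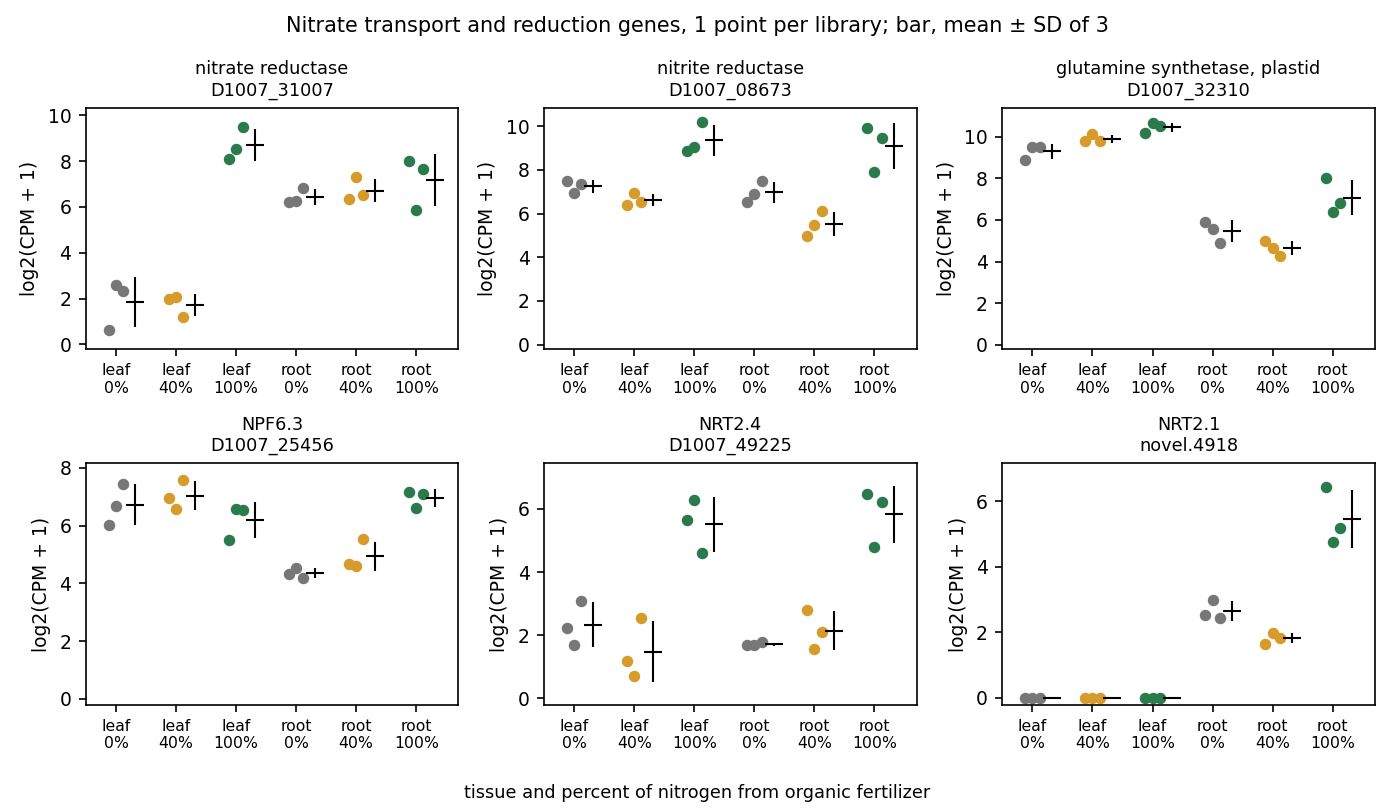
Levels of 6 genes of nitrate transport, nitrate reduction and ammonium assimilation, as log2(CPM + 1), at 0, 40 and 100% organic nitrogen in leaf and root; points are single libraries, and bars are the mean ± SD of 3 libraries. Nitrate reductase D1007_31007 in leaves averaged 3.21, 2.44 and 453 CPM at the 3 rates, and NPF6.3 D1007_25456 in roots averaged 19.4, 31.1 and 124 CPM.

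The lists of photosystems, the Calvin cycle, sulfate and heat shock passed the set test in the higher direction in leaves at 100% and that of ribosomal proteins in the lower, none of them with an estimated correlation. Of 69 tested genes of photosystems and light harvesting 22 rose and 2 fell (24 and 3 adjusted over the list alone, set-adjusted p = 0.000263; adjusted p = 0.8 with an estimated correlation). PsbS D1007_48858, which dissipates excess light energy, rose from 530 ± 66.5 to 4920 ± 815 CPM, and PSB28 D1007_55705, which assists photosystem II assembly, from 40.3 ± 10.9 to 377 ± 70.2 CPM. The summed level of the whole list did not follow these genes, since the 3 control leaves held 90000, 131000 and 69700 CPM and the 100% leaves 71300, 82300 and 105000 CPM. Of 36 Calvin cycle genes 18 rose and 8 fell (the same adjusted over the list alone, set-adjusted p = 0.018; adjusted p = 0.8 with an estimated correlation). Its 2 higher genes of smallest adjusted p were cytosolic fructose-1,6-bisphosphatase D1007_07770, of sucrose synthesis, at 1430 ± 28.7 against 236 ± 90.8 CPM, and glycerate kinase D1007_52816, of photorespiration, at 268 ± 19.9 against 72.5 ± 15.4 CPM. Of 29 genes of sulfate uptake and assimilation 9 rose and 1 fell (9 and 2 adjusted over the list alone, set-adjusted p = 0.0408; adjusted p = 0.8 with an estimated correlation). In it 5'-adenylylsulfate reductase 1 D1007_25844, the reducing step of sulfate assimilation, rose from 16.9 ± 5.98 to 1670 ± 331 CPM (6.87 ± 0.48, adjusted p = 0.00016). Ferredoxin-nitrite reductase is a member of the sulfate list by its annotation. The sulfate list passed no longer without control leaf 1 (0.092), 100% leaf 2 (0.085) or 100% leaf 3 (0.052). Under library size alone the calls were 20 higher and 5 lower in the photosystem list and 6 and 2 in the sulfate list.

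Of 176 heat shock genes 47 rose and 10 fell (49 and 10 adjusted over the list alone, set-adjusted p = 0.0114; adjusted p = 0.67 with an estimated correlation), or 39 and 20 under library size alone. The 17.9 kDa class I heat shock protein at SDOW01000171.1 (2011725 to 2080383, minus strand), a small chaperone, rose from 3.22 ± 0.497 to 94.5 ± 41.4 CPM (5.12 ± 0.38, adjusted p = 2e-04). Heat stress transcription factor A-2d D1007_16146 rose from 31.4 ± 9.63 to 356 ± 26.8 CPM, and the chaperone HSP70 D1007_49259, chosen after its values were seen, from 55 ± 2.02 to 854 ± 223 CPM. Of 322 ribosomal protein genes 18 rose and 49 fell (17 and 43 adjusted over the list alone, set-adjusted p = 0.000598; adjusted p = 0.8 with an estimated correlation), or 11 and 106 under library size alone. The 2 lower genes of smallest adjusted p were mitochondrial L21 D1007_30290, at 2.4 ± 0.292 against 13 ± 0.807 CPM, and an L18a-like gene D1007_18268. The latter had 2 counts over the 100% leaves and 152 over the controls, a ratio of 72.3 (95% counting interval 19.7 to 603).

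Of the 6 largest rises in leaves at 100% named by rule, 4 were those of early light-inducible proteins, chlorophyll-binding proteins of light stress, and the others those of a kinase and of NPF7.3. HV58 D1007_40217 had no count in control leaves and 288 ± 193 CPM at 100%, at least 1760-fold higher on a floor of 3 counts per library (adjusted p = 0.00056), or 1170-fold without 100% leaf 2. HV90 D1007_16608 was at least 592-fold higher (96.7 ± 136 CPM, adjusted p = 0.007), or 115-fold without 100% leaf 2. The HV90 locus at SDOW01000186.1 (4097998 to 4177859, minus strand) and the HV58 locus at SDOW01000614.1 (11314 to 12351, minus strand) rose by 9.02 ± 0.76 and 8.97 ± 0.85, the latter by 7.96 without 100% leaf 2. Mitogen-activated protein kinase kinase 9 D1007_54086, of stress signalling, was at least 38.6-fold higher, or 22.9-fold without 100% leaf 1. Among the largest falls, isocitrate lyase D1007_60153, of the glyoxylate cycle, had 359 ± 417 CPM in controls and no count at 100%, at least 2090-fold lower, or 755-fold without control leaf 3. The calcium-binding polcalcin D1007_00394 was at least 35.1-fold lower, or 21.3-fold without control leaf 3. Protochlorophyllide reductase A, of chlorophyll synthesis (SDOW01000729.1, 1087560 to 1089176, plus strand), was at 86.4 ± 141 against 0.0939 CPM. Its log2 change of -9.51 was -5.36 without control leaf 2, which held 249 CPM against 7.51 and 2.38 in the other controls. An acyltransferase-like gene D1007_33085 was at 290 ± 348 against 0.724 CPM, with a log2 change of -8.37, or -6.81 without control leaf 3. The cytokinin-activating LOGL9 D1007_60055 had 1240 counts against 2 (ratio 590, 95% counting interval 163 to 4880), a ratio of 889 without control leaf 2 and 352 without control leaf 3. Control leaf 2 stood apart from controls 1 and 3, with 2.78 CPM against 256 and 818 for isocitrate lyase, 1.55 against 191 and 677 for D1007_33085, and 0.321 against 26.5 and 41.8 for LOGL9. Expansin A2 D1007_35526, a wall-loosening protein, had 705 counts against 2 (ratio 335, 92.5 to 2780), and its control leaves held 0.16, 37.2 and 0.284 CPM. Without control leaf 2 its ratio was 5.76 and its log2 change went from -7.91 to -2.08, and without control leaf 1 the ratio was 507. The LOGL9 call (adjusted p = 0.017) was lost without control leaf 3 (0.054) or 100% leaf 2 (0.051). The expansin call (adjusted p = 0.033) was lost without control leaf 2 (0.2) or 100% leaf 1 (0.091), 2 (0.085) or 3 (0.077). In a fit with estimated library weights 7 of these calls were lost, and that fit gave the highest adjusted p of all alternatives. The alternatives ranged from 6.3e-05 to 0.16 for HV90 D1007_16608, 4.2e-07 to 0.37 for isocitrate lyase, 8.6e-06 to 0.44 for protochlorophyllide reductase A and 3.6e-07 to 0.35 for D1007_33085. They ranged from 0.0014 to 0.45 for LOGL9, 0.00056 to 0.55 for expansin A2 and 2.5e-05 to 0.088 for L18a-like D1007_18268.

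Leaves at 40% were compared with control leaves to ask which genes differed. A single gene rose and a single gene fell of 20032 tested. LOGL5 D1007_47842, which activates cytokinins (SDOW01000718.1, 1339076 to 1339822, plus strand), rose from 12.2 ± 2.32 to 54.9 ± 3.27 CPM (2.17 ± 0.22, adjusted p = 0.023). Phosphoglycerate dehydrogenase D1007_22029, the first step of serine synthesis in plastids (SDOW01000218.1, 880861 to 883866, minus strand), fell from 60.3 ± 4.68 to 14.9 ± 0.742 CPM (-2.02 ± 0.21, adjusted p = 0.023). Photosystem and light-harvesting genes passed as a set in the higher direction (adjusted p = 1.61e-12, and adjusted p = 0.8 with an estimated correlation), with 0 of 69 called over all genes and 18 higher and 2 lower adjusted over the list alone. Calvin cycle genes did so too (0 of 36 called, 8 higher and 1 lower adjusted over the list alone, set-adjusted p = 0.0202; adjusted p = 0.8 with an estimated correlation). The Calvin set passed no longer without control leaf 1 (0.099) or 40% leaf 1 (0.058).

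No nitrogen list passed in leaves at 40%, and 0 of its members were called by edgeR. Adjusted over the list alone, the nitrate transport list had 3 genes higher and 4 lower (set-adjusted p = 0.367), the NPF list 5 and 9 (set-adjusted p = 0.241) and the assimilation list 1 and 1 (set-adjusted p = 0.95). The amino acid and oligopeptide list had 0 and 2 (set-adjusted p = 0.641), the urea and ureide list 1 and 4 (set-adjusted p = 0.571) and the 3 ammonium transporters 0 and 0. The assimilation list had a median of -0.13 and a mean of -0.09 while its set test pointed upward. Glutamine synthetase D1007_38808 was at 445 ± 71.9 CPM against 1600 ± 856 (adjusted p = 0.1). DUR3 D1007_41289 was at 15.5 ± 4.01 against 101 ± 61.4 (adjusted p = 0.093) and oligopeptide transporter 7 D1007_44798 at 19.7 ± 1.15 against 154 ± 93.6 (adjusted p = 0.09). These 3 were chosen after their values were seen. The most abundant members were not called either, with adjusted p of 0.11 for NPF6.4 D1007_17999, 0.22 for AMT2;1 D1007_10500, 0.27 for glutamine synthetase D1007_32310, 0.22 for D1007_39707 and 0.8 for allantoate deiminase D1007_57662. Unadjusted, 3635 genes had a p below 0.05, and the count of calls was 1585 with DESeq2 and 2123 with limma voom and sample weights. Both named calls were lost without control leaf 1 (0.14 each), control leaf 3 (0.15 each), or 40% leaf 1 (0.24 for D1007_22029 and 0.21 for D1007_47842), 2 (0.16 each) or 3 (0.19 and 0.17), with 0 genes called in each of these fits. Without control leaf 2 the count was 1035. Over all alternatives the adjusted p ranged from 3.8e-16 to 0.24 for D1007_22029 and from 5.3e-16 to 0.21 for D1007_47842. Control leaf 2 correlated at 0.922 with the 40% leaves and at 0.917 with the other control leaves, on average across genes, which are not independent replicates.

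Leaves at 100% were compared with leaves at 40% to ask which genes differed. Nitrate reductase D1007_31007 rose from 2.44 ± 1.04 to 453 ± 234 CPM (7.78 ± 0.86, adjusted p = 0.00095) and ferredoxin-nitrite reductase D1007_08673 from 98.5 ± 19.9 to 716 ± 386 CPM (3.11 ± 0.40, adjusted p = 0.0017). NPF6.4 D1007_17999 rose from 175 ± 15.7 to 561 ± 98.7 CPM (1.93 ± 0.26) and NPF8.3 D1007_22593 by 3.27 ± 0.41, whereas NPF8.3 D1007_24918 fell from 48.5 ± 5.31 to 10.8 ± 2 CPM. Of 20032 genes 3730 were called, 2224 higher and 1506 lower, and 6923 had an unadjusted p below 0.05. The count was 1501 without 40% leaf 1, 2046 without 40% leaf 2 and 1934 without 40% leaf 3, and library size alone made 36.9% of the calls higher against 59.6%. No nitrogen list passed. Counts higher and lower were 8 and 5 for nitrate transport (10 and 7 adjusted over the list alone, set-adjusted p = 0.884), 10 and 6 for NPF (12 and 9, set-adjusted p = 0.836) and 2 and 2 for assimilation (4 and 2, set-adjusted p = 0.747). They were 9 and 5 for amino acids and oligopeptides (9 and 5, set-adjusted p = 0.992), 2 and 3 for urea and ureides (2 and 5, set-adjusted p = 0.836) and 0 and 0 for the 3 ammonium transporters. The nitrate list had a median of -0.07 and a mean of 0.23, and the urea list a median of -0.29 and a mean of 0.16. The most abundant uncalled members were glutamine synthetase D1007_32310 (adjusted p = 0.064), D1007_39707 (0.1) and AMT2;1 D1007_10500 (0.32). Allantoate deiminase D1007_57662 rose from 193 ± 35.7 to 764 ± 564 CPM (adjusted p = 0.034), a call lost without 40% leaf 1 (0.12), 2 (0.076) or 3 (0.11) or 100% leaf 1 (0.1), with alternatives of 0.0011 to 0.12. Its log2 change went from 2.24 to 1.45 without 100% leaf 1.

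Of 176 heat shock genes 46 were higher at 100% than at 40% and 7 lower (52 and 13 adjusted over the list alone, set-adjusted p = 0.0175; adjusted p = 0.59 with an estimated correlation), or 34 and 16 under library size alone. The 17.9 kDa heat shock protein at SDOW01000171.1 rose by 5.02 ± 0.38 from 3.45 ± 0.35 CPM. Of 322 ribosomal protein genes 10 rose and 25 fell (5 and 13 adjusted over the list alone, set-adjusted p = 0.0175; adjusted p = 0.97 with an estimated correlation), or 5 and 58 under library size alone. L21 D1007_30290 was at 2.4 ± 0.292 against 11.9 ± 1.19 CPM. The heat shock set passed no longer without 40% leaf 1 (0.064), 40% leaf 2 (0.073) or 100% leaf 3 (0.12), nor the ribosomal set without 40% leaf 2 (0.099) or 100% leaf 1 (0.41). HV90 D1007_16609 had 8012 counts at 100% and 3 at 40%, a ratio of 2660 (95% counting interval 910 to 12900), or 1430 without 100% leaf 2. NCED3 D1007_36972, which makes the precursor of abscisic acid, was at least 106-fold higher, with 15.7, 38.9 and 0.339 CPM in the 100% leaves, or 46.4-fold without 100% leaf 2. The phosphodiesterase GDPD2 D1007_09643 was at least 61.2-fold higher. Ubiquitin ligase RMA3 D1007_41921 was at least 127-fold lower, the protease nepenthesin D1007_42449 at least 119-fold lower and lipid-transfer protein 4.1 D1007_37227 at least 110-fold lower. Without 40% leaf 1, 2 and 3 in turn the adjusted p was 0.059, 0.052 and 0.052 for NCED3 and 0.06, 0.054 and 0.051 for lipid-transfer protein 4.1. That of nepenthesin was 0.061 without leaf 1 and 0.055 without leaf 2, and that of RMA3 was 0.052 without leaf 1. With estimated library weights 3 of these calls were lost. The alternatives ranged from 5.8e-06 to 0.12 for NCED3, 0.00019 to 0.23 for lipid-transfer protein 4.1, 0.00018 to 0.084 for nepenthesin and 4e-06 to 0.052 for RMA3.

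Roots at 100% were compared with control roots to ask which genes differed. The nitrate carrier and sensor NPF6.3 D1007_25456 (SDOW01000262.1, 1234218 to 1240330, minus strand) rose from 19.4 ± 2.4 to 124 ± 24.7 CPM. The high-affinity nitrate carrier NRT2.4 D1007_49225 (SDOW01000759.1, 1375685 to 1378954, plus strand) rose from 2.27 ± 0.125 to 62.8 ± 31.8 CPM. Nitrate reductase D1007_08787 (SDOW01000066.1, 7720677 to 7724047, plus strand) rose from 163 ± 25.5 to 667 ± 101 CPM. HSP70 D1007_49259 rose, and peroxidase 2 D1007_55047 and glutathione S-transferase U17 D1007_33860 fell. Of 21895 genes tested 2240 (10.2%) were called, 1027 higher and 1213 lower, and 6166 had an unadjusted p below 0.05. The balance turned in some fits, since 45.8% of the calls were higher, but 53.1% under library size alone, 50.6% with voom and sample weights and 52.7% without 100% root 2, and 40.2 and 39.6% without control root 1 and 2. The count was 1129, 571 and 909 without control root 1, 2 and 3 in turn, 1074 without 100% root 1 and 788 without 100% root 3.

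Genes of nitrate reduction and ammonium assimilation rose as a set: 5 of 19 rose and 0 fell (8 and 1 adjusted over the list alone, set-adjusted p = 0.00715; adjusted p = 0.7 with an estimated correlation). Nitrate reductase D1007_08787 rose by 1.99 ± 0.24 (adjusted p = 0.0026, alternatives 9.5e-13 to 0.069, the last with all 18 libraries in 1 fit). Ferredoxin-nitrite reductase D1007_08673 was at 637 ± 370 against 130 ± 44.6 CPM (adjusted p = 0.027). NADH-glutamate synthase D1007_59671, which makes glutamate from glutamine, was at 597 ± 419 against 129 ± 55 CPM (adjusted p = 0.044) and cytosolic glutamine synthetase D1007_33459 at 893 ± 522 against 302 ± 95.3 CPM (adjusted p = 0.045). These 3 and the uncalled asparagine synthetase D1007_37625 (865 ± 560 against 279 ± 100 CPM, adjusted p = 0.091) were chosen after their values were seen. Glutamine synthetase D1007_38808, the most abundant member in roots, was at 2250 ± 366 against 1690 ± 107 CPM (adjusted p = 0.32). The nitrite reductase call (alternatives 8.3e-05 to 0.11) was lost without control root 1 (0.087) or 2 (0.11) or 100% root 1 (0.079) or 3 (0.075). Without control root 1, 2 and 3 and 100% root 1 and 3 in turn, the adjusted p was 0.13, 0.15, 0.062, 0.13 and 0.09 for glutamate synthase and 0.08, 0.14, 0.13, 0.12 and 0.068 for glutamine synthetase D1007_33459. Over all alternatives it ranged from 0.013 to 0.15 and from 0.0019 to 0.18. Without 100% root 1 the log2 change went from 2.15 to 1.40 for glutamate synthase and from 1.56 to 0.92 for D1007_33459.

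Transport lists had calls in both directions in roots. Nitrate transport had 9 genes higher and 9 lower of 79 (14 and 12 adjusted over the list alone, set-adjusted p = 0.553) and NPF 7 and 9 of 90 (13 and 10, set-adjusted p = 0.553). NPF6.3 D1007_25456 rose by 2.63 ± 0.26 (adjusted p = 0.0011) and NRT2.4 D1007_49225 by 4.74 ± 0.52 (adjusted p = 0.0016). The NRT2.1 locus at SDOW01001366.1 (141171 to 143912, minus strand) rose by 3.16 ± 0.44, or 2.43 without 100% root 1, from 5.38 ± 1.41 to 48.7 ± 31.9 CPM. NPF8.3 D1007_24918 fell from 32.7 ± 7.05 to 15.9 ± 1.85 CPM. The NPF8.3 locus at SDOW01000473.1 (650525 to 652841, plus strand) fell from 224 ± 18.8 to 69.9 ± 25.2 CPM (adjusted p = 0.01, alternatives 1.6e-06 to 0.088, the last with all 18 libraries in 1 fit). NPF5.6 D1007_33979 had 1 count at 100% and 88 in controls, a ratio of 83 (95% counting interval 14.5 to 3310). The most abundant members, the NRT2 partner NAR2.2 D1007_44398 and the NPF2.11 locus at SDOW01000018.1 (8101275 to 8105360, plus strand), were not called (adjusted p = 0.41 and 0.35). Of 6 ammonium transporters 1 rose and 1 fell (1 and 2 adjusted over the list alone, set-adjusted p = 0.553). AMT2;1 D1007_10500 fell from 110 ± 11.1 to 67.2 ± 9.13 CPM (adjusted p = 0.016). AMT3;1 D1007_48840, chosen after its values were seen, was at 3.17 ± 2.92 against 24.6 ± 16.9 CPM (adjusted p = 0.092). The AMT2;1 call was lost without control root 2 (0.051) or 3 (0.051) and with all 18 libraries in 1 fit (0.41), with alternatives from 0.00013 up.

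Of 100 amino acid and oligopeptide transporters 8 rose and 5 fell in roots (11 and 8 adjusted over the list alone, set-adjusted p = 0.713). Both of those named are YSL6, annotated as carriers of metal chelates. D1007_15838 was at least 15.4-fold higher (2.82 ± 1.68 CPM against no count), or 10.1-fold without 100% root 1, and D1007_42769 rose from 0.488 ± 0.277 to 7.09 ± 3.15 CPM (adjusted p = 0.004, alternatives 6.7e-10 to 0.12, the last with all 18 libraries in 1 fit). The most abundant member D1007_39707 was not called (adjusted p = 0.21). In the urea and ureide list 1 of 14 rose and 1 fell (3 and 4 adjusted over the list alone, set-adjusted p = 0.989). Urease accessory protein G D1007_32185 fell from 51.8 ± 8.7 to 28 ± 3.92 CPM (adjusted p = 0.011, alternatives 4.7e-05 to 0.051, the last without control root 2). Allantoate deiminase D1007_57662 was at 612 ± 145 against 320 ± 110 CPM (adjusted p = 0.052).

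Of 199 heat shock genes 41 rose and 7 fell in roots (49 and 9 adjusted over the list alone, set-adjusted p = 6.69e-05; adjusted p = 0.27 with an estimated correlation). HSP70 D1007_49259 rose from 85.4 ± 5.96 to 1360 ± 67.3 CPM (3.95 ± 0.20, adjusted p = 2.6e-05) and the cognate D1007_59521 from 9.43 ± 0.821 to 134 ± 27.4 CPM. The small heat shock protein D1007_18370 rose from 0.0806 to 9.96 ± 6.95 CPM, by a log2 change of 6.77, or 6.09 without 100% root 2. A pair of 16.9 kDa heat shock loci that overlap on opposite strands at SDOW01000454.1 (4575448 to 4604346, plus, and 4575448 to 4604148, minus) rose by 5.77 ± 0.79 and 5.12 ± 0.66. Their separate levels are uncertain because the handling of strands is not given in the sources used here. Heat stress factor A-2d D1007_16146, chosen after its values were seen, was at 109 ± 40.7 against 64 ± 12.1 CPM (adjusted p = 0.13).

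The lists of WRKY factors, of peroxidases and glutathione S-transferases, and of ethylene genes passed in the lower direction in roots, none of them with an estimated correlation. Of 81 WRKY transcription factors 0 rose and 14 fell (0 and 21 adjusted over the list alone, set-adjusted p = 0.00378; adjusted p = 0.28 with an estimated correlation). D1007_35544, annotated WRKY46, fell from 18 ± 5.05 to 3.15 ± 0.807 CPM and WRKY51 D1007_00267 from 7.71 ± 0.861 to 1.19 ± 0.377 CPM (adjusted p = 0.0056, alternatives 4.2e-08 to 0.13, the last with all 18 libraries in 1 fit). Of 175 peroxidases and glutathione S-transferases 7 rose and 33 fell (9 and 38 adjusted over the list alone, set-adjusted p = 0.00378; adjusted p = 0.58 with an estimated correlation). Peroxidase 2 D1007_55047 fell from 12.1 ± 2.47 to 0.324 ± 0.192 CPM and glutathione S-transferase U17 D1007_33860 from 176 ± 60.8 to 34.3 ± 11.9 CPM. Of 148 ethylene genes 5 rose and 16 fell (8 and 23 adjusted over the list alone, set-adjusted p = 0.0234; adjusted p = 0.86 with an estimated correlation). ERF020 D1007_13819 fell by 3.50 (SE 0.51) and ERF1B D1007_40459 fell by 2.37 (SE 0.41), both transcription factors, on the log2 scale. Their adjusted p over alternatives ranged from 5.2e-10 to 0.061 and from 3.1e-06 to 0.12, the highest with all 18 libraries in 1 fit. The peroxidase set passed no longer without control root 3 (0.075) or 100% root 2 (0.1), nor the ethylene set without control root 3 (0.23) or 100% root 3 (0.11).

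The largest rises in roots at 100% included cation/proton antiporter 20 D1007_11312, from 0.286 ± 0.16 to 84.9 ± 70.6 CPM (8.15 ± 0.93, adjusted p = 0.002), or by 7.29 without 100% root 2. LIFEGUARD 4 D1007_05196, of a family that inhibits cell death, rose from 1.04 ± 0.495 to 32.9 ± 9.05 CPM, and D1007_38814, annotated chalcone synthase A, from 0.241 ± 0.18 to 10.7 ± 11.9 CPM. The largest falls included a pair of clock-related genes, PCL1 D1007_45039 from 22.6 ± 5.43 to 0.524 ± 0.522 CPM (adjusted p = 0.0024) and the histone demethylase JMJ30 D1007_26028 from 5.08 ± 0.552 to 0.129 ± 0.0618 CPM (adjusted p = 0.00059). Laccase 9 D1007_56949, of lignin polymerisation, fell from 34.2 ± 3.91 to 0.31 ± 0.537 CPM and flavone O-methyltransferase D1007_22362 from 29.6 ± 25.1 to 0.591 ± 0.32 CPM. RAFTIN 1A D1007_09916 fell from 12.4 ± 9.6 to 0.0832 ± 0.0947 CPM and a glycine-rich wall protein D1007_23958 from 10.6 ± 3.3 to 0.195 ± 0.115 CPM. The call of LIFEGUARD 4 was lost without control root 2 (0.062) and that of D1007_38814 without control root 1 (0.061), 2 (0.082) or 3 (0.051). That of laccase 9 was lost without control root 2 (0.052) or 100% root 1 (0.054) and that of the methyltransferase without 100% root 3 (0.05). The alternatives ranged from 3.2e-06 to 0.062 for LIFEGUARD 4 and 2.9e-07 to 0.082 for D1007_38814. They ranged from 4.7e-07 to 0.092 for the methyltransferase and 2.1e-05 to 0.14 for RAFTIN 1A, the highest with estimated library weights, and from 0.0021 to 0.056 for laccase 9, the highest with all 18 libraries in 1 fit. The log2 change of D1007_38814 went from 5.32 to 3.93 without 100% root 3 and that of the methyltransferase from -5.75 to -4.80 without control root 3.

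**Figure D3:**
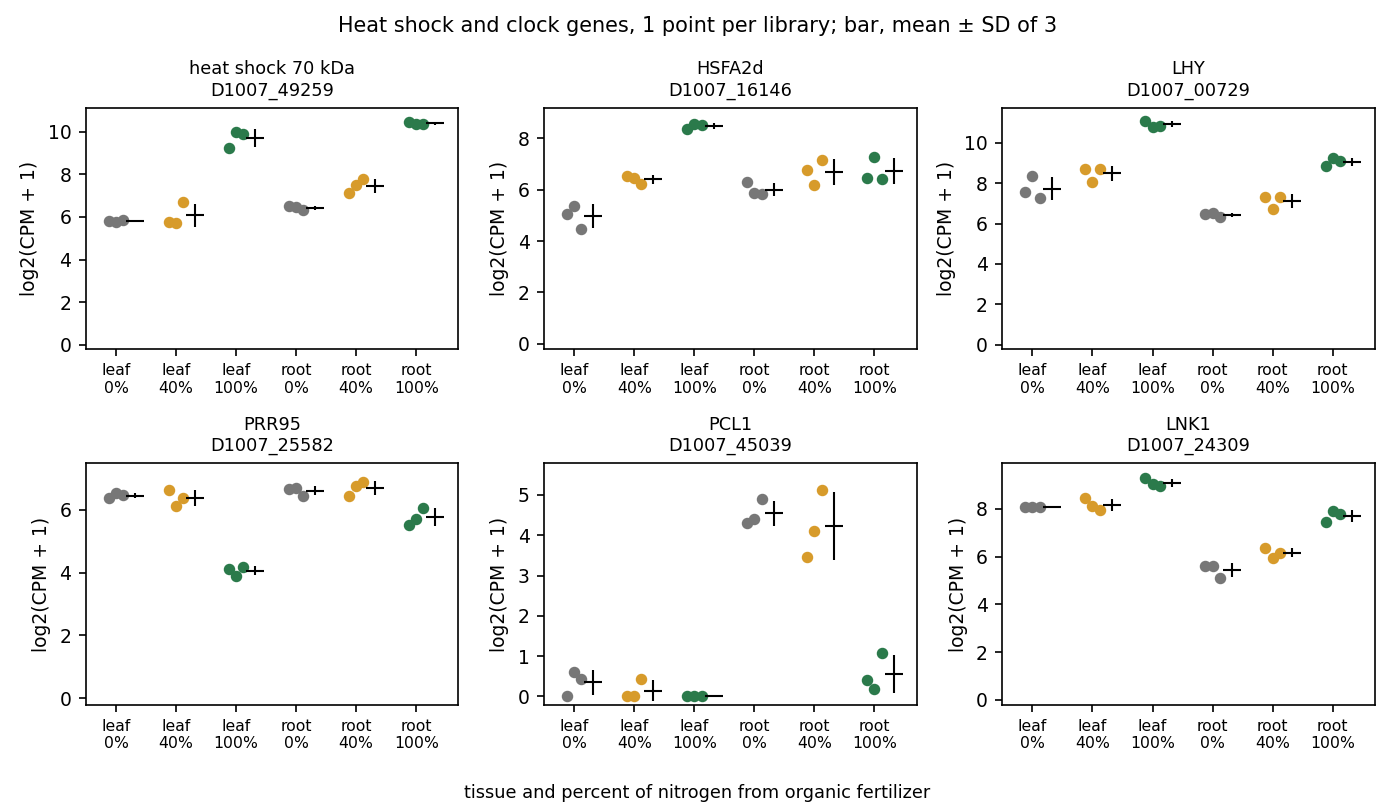
Levels of clock and heat shock genes, as log2(CPM + 1), at 0, 40 and 100% organic nitrogen in leaf and root; points are single libraries, and bars are the mean ± SD of 3 libraries. HSP70 D1007_49259 averaged 55, 69.3 and 854 CPM in leaves and 85.4, 178 and 1360 CPM in roots, and the clock gene LHY D1007_00729 averaged 223, 362 and 1930 CPM in leaves and 85.2, 140 and 533 CPM in roots.

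Roots at 40% were compared with control roots to ask which genes differed. The 3 cellulose synthases of secondary walls were among the 6 largest rises. CESA4 D1007_03347 (SDOW01000025.1, 685220 to 690589, minus strand) rose from 3.36 ± 1.7 to 42.1 ± 23.4 CPM (3.59 ± 0.48, adjusted p = 0.033). CESA9 D1007_24041 (SDOW01000243.1, 4800713 to 4805348, minus strand) rose from 5.75 ± 1.08 to 61 ± 41.6 CPM (3.37 ± 0.44, adjusted p = 0.033) and CESA7 D1007_35265 (SDOW01000418.1, 768951 to 773373, minus strand) from 3.27 ± 2 to 35.3 ± 17.8 CPM (3.37 ± 0.53, adjusted p = 0.044). TBL32, which acetylates xylan (locus SDOW01000129.1, 5882312 to 5885198, plus strand), rose from 2.33 ± 0.606 to 17.7 ± 12 CPM. A glucanase D1007_54310 rose from 1.36 ± 0.411 to 11.6 ± 3.66 CPM and D1007_30337, annotated ferric-chelate reductase, from 0.468 ± 0.102 to 9.84 ± 4.41 CPM (adjusted p = 0.017). The lipid-transfer protein DIR1 D1007_29784, of systemic defence signals, fell from 3820 ± 1430 to 739 ± 217 CPM and purple acid phosphatase 27 D1007_44145 from 97.1 ± 26.7 to 19.9 ± 3.59 CPM. ACC oxidase D1007_56540, the last step of ethylene synthesis, fell from 100 ± 51.7 to 19.8 ± 3.03 CPM. Peroxidase 2 D1007_55047 fell by 3.53 (SE 0.48) on the log2 scale, and the lectin receptor kinase D1007_23537 fell from 7.15 ± 1.28 to 1.27 ± 0.686 CPM. The aspartyl protease D1007_49696 had 739 counts in controls and 2 at 40%, a ratio of 321 (95% counting interval 88.5 to 2650), or 209 without control root 1. Of 21895 genes 67 were called, 36 higher and 31 lower, and 3295 had an unadjusted p below 0.05. The count was 21 without control root 1 (5 higher and 16 lower), 0 without control root 2 or 3, 151 without 40% root 1 (112 and 39), 12 without 40% root 2 (10 and 2) and 44 without 40% root 3 (31 and 13). Of the 12 named calls, 8 were lost without control root 1 (adjusted p 0.052 to 0.1), 12 without control root 2 (0.19 to 0.24), and 12 without control root 3 (0.083 to 0.13). Of the same 12, 2 were lost without 40% root 1 (0.059 and 0.068), 9 without 40% root 2 (0.06 to 0.14) and 8 without 40% root 3 (0.055 to 0.093). Over all alternatives the adjusted p ranged from 1.4e-11 to 0.3 for CESA4, 4.3e-12 to 0.25 for CESA9, 1.9e-08 to 0.38 for CESA7 and 6.8e-15 to 0.25 for D1007_30337. Without 40% root 1 the log2 change of CESA9 was 2.67, and that of TBL32 went from 2.88 to 2.23.

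Ribosomal protein genes were lower as a set in roots at 40%, by a median log2 change of -0.24 over 327 genes (set-adjusted p = 5.19e-11; adjusted p = 0.78 with an estimated correlation), with 0 called over all genes and 0 adjusted over the list alone. Cytokinin genes were lower as a set too (0 of 68 called, 1 higher and 6 lower adjusted over the list alone, set-adjusted p = 0.00275; adjusted p = 0.78 with an estimated correlation). The cytokinin set passed no longer without 40% root 2 (0.063). No member of the 6 nitrogen lists was called by edgeR. Adjusted over the list alone there were 2 higher and 0 lower of 79 nitrate transport genes (set-adjusted p = 0.274), 5 and 2 of 90 genes of the NPF list (set-adjusted p = 0.814) and 1 and 2 of 6 ammonium transporters (set-adjusted p = 0.666). There were 0 and 0 of 19 assimilation genes (set-adjusted p = 0.551), 2 and 1 of 100 amino acid and oligopeptide transporters (set-adjusted p = 0.587) and 1 and 0 of 14 urea and ureide genes (set-adjusted p = 0.551). The NPF list had a median of 0.05 and a mean of -0.06, and the ammonium list a median of 0.02 and a mean of -1.73. The nitrogen genes of largest mean level had adjusted p of 0.21 (AMT2;1 D1007_10500), 0.13 (D1007_39707), 0.39 (glutamine synthetase D1007_38808), 0.8 (NAR2.2 D1007_44398), 0.34 (the NPF2.11 locus) and 0.94 (allantoate deiminase D1007_57662). AMT3;1 D1007_48840, chosen after its values were seen, was at 0.328 ± 0.567 against 24.6 ± 16.9 CPM (adjusted p = 0.083). DESeq2 called 1155 genes between these groups and limma voom with sample weights 484.

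**Figure D4:**
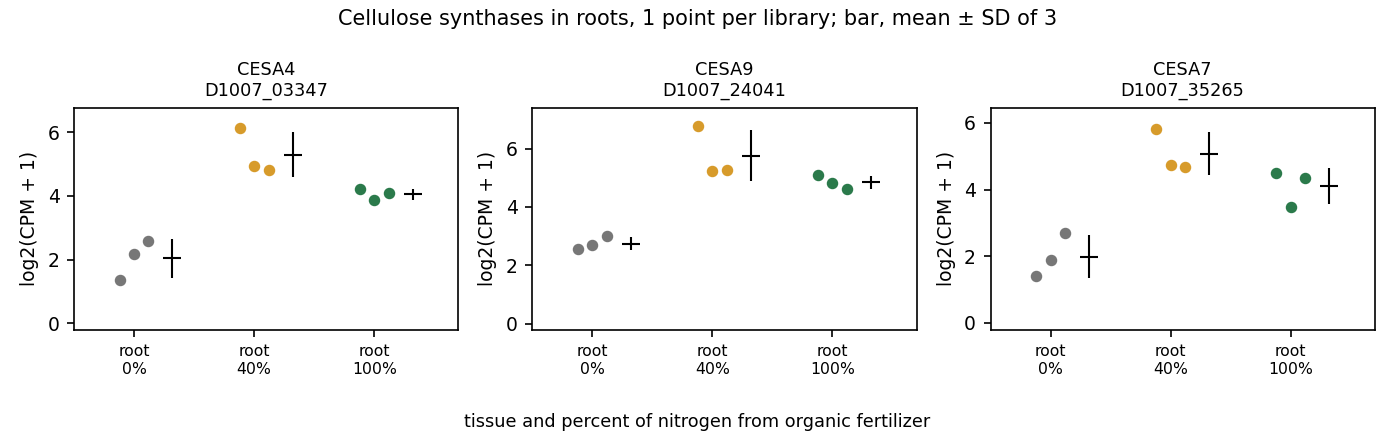
Levels of the secondary wall cellulose synthases CESA4, CESA9 and CESA7 in roots, as log2(CPM + 1), at 0, 40 and 100% organic nitrogen; points are single libraries, and bars are the mean ± SD of 3 libraries. CESA4 averaged 3.36, 42.1 and 15.7 CPM at the 3 rates, CESA7 3.27, 35.3 and 17 CPM and CESA9 5.75, 61 and 27.9 CPM.

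Roots at 100% were compared with roots at 40% to ask which genes differed. The NRT2.1 locus at SDOW01001366.1 rose from 2.55 ± 0.394 to 48.7 ± 31.9 CPM (4.24 ± 0.47, adjusted p = 0.0035), or by 3.51 without 100% root 1. NRT2.4 D1007_49225 rose from 3.69 ± 2.03 to 62.8 ± 31.8 CPM (4.07 ± 0.50, adjusted p = 0.0045) and NPF6.3 D1007_25456 from 31.1 ± 12 to 124 ± 24.7 CPM (1.98 ± 0.26, adjusted p = 0.0057). AMT2;1 D1007_10500 fell from 150 ± 19.1 to 67.2 ± 9.13 CPM (adjusted p = 0.0053, alternatives 2.2e-10 to 0.28, the last with all 18 libraries in 1 fit). Non-symbiotic hemoglobin D1007_04718, which scavenges nitric oxide, rose from 1.16 ± 1.17 to 90 ± 51.1 CPM (6.29 ± 0.92, adjusted p = 0.009), or by 5.70 without 40% root 1. Cation/proton antiporter 20 D1007_11312 rose from 2.67 ± 1.85 to 84.9 ± 70.6 CPM, by a log2 change of 4.97, or 4.11 without 100% root 2. Of 21895 genes 1005 were called, 526 higher and 479 lower, and 4865 had an unadjusted p below 0.05. Of the calls 52.3% were higher, but 49.3% with DESeq2 and 43.9, 44.8 and 43.3% without 40% root 1, 2 and 3, and 63.1% without 100% root 2. The count was 435 without 40% root 1, 319 without 40% root 2, 310 without 100% root 1 and 209 without 100% root 3. The glucosyltransferase D1007_22249 rose by 4.52 ± 0.87 (adjusted p = 0.026). PCL1 D1007_45039 fell by 5.24 (SE 0.65), JMJ30 D1007_26028 fell by 5.55 (SE 0.48) and the oxidase RBOH-B D1007_56555, a source of superoxide, fell by 4.49 (SE 1.04, adjusted p = 0.042). The glucosyltransferase call was lost without 40% root 2 (0.071), 100% root 1 (0.068) or 100% root 3 (0.068). That of RBOH-B was lost without 40% root 1 (0.1) or 2 (0.092) or 100% root 1 (0.13), 2 (0.071) or 3 (0.055). Their alternatives ranged from 0.00034 to 0.078 and from 0.0089 to 0.16, and the RBOH-B change was -3.67 without 40% root 1.

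The assimilation list rose as a set again, with 5 of 19 higher and 0 lower (7 and 0 adjusted over the list alone, set-adjusted p = 0.000391; adjusted p = 0.53 with an estimated correlation). Heat shock genes did so with 24 of 199 higher and 0 lower (34 and 3 adjusted over the list alone, set-adjusted p = 0.000391; adjusted p = 0.41 with an estimated correlation). HSP70 D1007_49259 rose by 2.91 ± 0.19. Of 175 peroxidases and glutathione S-transferases 2 rose and 20 fell (4 and 30 adjusted over the list alone, set-adjusted p = 0.000513; adjusted p = 0.51 with an estimated correlation). Peroxidase 70 D1007_37657 fell from 33.5 ± 4.49 to 13.4 ± 1.86 CPM. Of 122 phenylpropanoid and lignin genes 0 rose and 11 fell (2 and 16 adjusted over the list alone, set-adjusted p = 0.0065; adjusted p = 0.58 with an estimated correlation). Putrescine hydroxycinnamoyltransferase D1007_53663 fell from 79.8 ± 11.1 to 33.5 ± 1.57 CPM. The ribosomal list passed in the higher direction with 4 of 327 higher (1 adjusted over the list alone, set-adjusted p = 0.000391; adjusted p = 0.77 with an estimated correlation). Its named member D1007_16636 is annotated by its protein match as S-adenosylmethionine decarboxylase, of polyamine synthesis. In the nitrogen lists that did not pass, counts higher and lower were 9 and 6 for nitrate transport (10 and 13 adjusted over the list alone, set-adjusted p = 0.93), 6 and 6 for NPF (8 and 15, set-adjusted p = 0.724) and 0 and 1 for ammonium transport (1 and 1, set-adjusted p = 0.93). They were 4 and 2 for amino acids and oligopeptides (5 and 2, set-adjusted p = 0.987) and 0 and 0 for urea and ureides (1 and 3, set-adjusted p = 0.564). The nitrate list had a median of -0.15 and a mean of 0.03, and the amino acid list a median of -0.05 and a mean of 0.08, and both set tests pointed upward. The uncalled genes of largest mean level had adjusted p of 0.066 (the NPF2.11 locus), 0.062 (allantoate deiminase D1007_57662), 0.88 (glutamine synthetase D1007_38808), 0.77 (NAR2.2 D1007_44398) and 0.36 (D1007_39707).

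The responses of leaf and root were compared by gene in a fit of shared spread, as root change minus leaf change. At 100% against the control, nitrate reductase D1007_31007 had a difference of -6.54 on the log2 scale and adenylylsulfate reductase D1007_25844 of -7.40, the latter -8.86 without replicate 1 of every group and -6.43 without replicate 3. NPF6.3 D1007_25456 had a difference of 2.89 and uricase D1007_27011 of 2.56. Of 24046 genes tested the tissues differed at 3827, of which 1732 had the higher change in root and 2095 the higher change in leaf. At 40% against the control they differed at 456 genes, 294 and 162, among them glutamine synthetase D1007_38808 (2.28), DUR3 D1007_41289 (3.11) and ACC oxidase D1007_56540 (-3.75). The counts were 627 at 100% without replicate 1 of every group, 1745 without replicate 2 and 1398 without replicate 3, and 0, 309 and 0 at 40%, where it was 1348 without control leaf 2. Without replicate 1, 2 and 3 of every group in turn, the adjusted p at 40% was 0.26, 0.073 and 0.35 for glutamine synthetase D1007_38808, 0.21, 0.057 and 0.35 for DUR3 and 0.15, 0.099 and 0.24 for ACC oxidase. Unadjusted, 7351 genes at 100% and 4365 at 40% had a p below 0.05. Of 18145 genes tested in both tissues 543 were called in both at 100% against the control. Of these 215 were higher in both (104 expected of independent calls), 172 lower in both (98.9), 90 higher in leaf and lower in root (112) and 66 the reverse (92.3). Heat shock genes gave 25 of 171 higher in both tissues and 1 lower in both.

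Leaf and root were compared at 0% organic nitrogen as a background for the tissue contrast. AMT2;1 D1007_10500 was at 110 ± 11.1 CPM in control roots and 39.7 ± 19.4 CPM in control leaves, and glutamine synthetase D1007_38808 at 1690 ± 107 and 1600 ± 856 CPM. Of 24046 genes 13506 differed between the tissues, 6221 higher in leaf and 7285 higher in root, and 14632 had an unadjusted p below 0.05.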

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

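The tests in this part were planned, while D1007_24309, D1007_25582, D1007_37625, D1007_38808, D1007_41289 and D1007_44798 were chosen after their values were seen, as were leaving out 1 split at 100% and the fits without control leaf 2 alone. The results here are those at which the change in root and the change in leaf differed by a test of the difference itself. Values are root change minus leaf change on the log2 scale.

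At 40% against the control the tissues differed at 456 genes. The difference was positive for the nitrogen genes NPF6.4 D1007_17999 (1.69), glutamine synthetase D1007_38808 (2.28), cationic amino acid transporter 2 D1007_39707 (1.66), DUR3 D1007_41289 (3.11) and oligopeptide transporter 7 D1007_44798 (3.33). It was negative for lectin receptor kinase D1007_23537 (-2.25), purple acid phosphatase 27 D1007_44145 (-3.82) and ACC oxidase D1007_56540 (-3.75). Leaving out replicate 1 of every group ended 8 of these 8 calls (adjusted p 0.12 to 0.26), replicate 2 ended 5 (0.057 to 0.1) and replicate 3 ended 8 (0.24 to 0.39), while leaving out control leaf 2 alone ended 0. The count was then 0, 309, 0 and 1348 genes. Of 40 drawn splits, the real one called 456 genes and the highest other 2. As mixing labels adds spread, this cannot exclude chance.

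At 100% against the control the tissues differed at 3827 genes. In nitrogen transport and metabolism the difference was positive for NPF6.3 D1007_25456 (2.89), NPF8.3 D1007_24918 (1.68), NPF5.1 D1007_28888 (3.09), uricase D1007_27011 (2.56), the urease accessory protein F locus at SDOW01000586.1 (1.14), asparagine synthetase D1007_37625 (4.66), glutamine synthetase D1007_38808 (2.49), D1007_39707 (1.81), DUR3 D1007_41289 (2.35) and oligopeptide transporter 7 D1007_44798 (2.09). It was negative for nitrate reductase D1007_31007 (-6.54), NPF7.3 D1007_00549 (-8.17), NPF4.6 D1007_29299 (-3.3) and YPQ1 D1007_00095 (-2.75). Nitrate reductase D1007_31007 was called in leaf and not in root (0.91, adjusted p = 0.26), and NPF6.3 in root and not in leaf (-0.31, adjusted p = 0.62).

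In photosynthesis, sulfate and light stress it was negative for adenylylsulfate reductase D1007_25844 (-7.4), fructose-1,6-bisphosphatase D1007_07770 (-2.55), glycerate kinase D1007_52816 (-2.08), HV58 D1007_40217 (-17.25), the HV90 locus at SDOW01000186.1 (-6.31) and the kinase D1007_54086 (-10.38). Among heat shock and clock genes it was negative for heat stress factor A-2d D1007_16146 (-3.05) and the 17.9 kDa heat shock locus at SDOW01000171.1 (-2.39), and positive for LNK1 D1007_24309 (0.93) and PRR95 D1007_25582 (1.28). It was also negative for ERF020 D1007_13819 (-10.21) and glutathione S-transferase U17 D1007_33860 (-4.71). It was positive for the antiporter D1007_11312 (5.45), the ribosomal genes D1007_18268 (3.3) and D1007_30290 (2.37), the acyltransferase D1007_33085 (9.69), expansin A2 D1007_35526 (9.85), LOGL9 D1007_60055 (9.44) and isocitrate lyase D1007_60153 (17.69). For PsbS D1007_48858 in roots (0.12 and 0.0422 CPM) and JMJ30 D1007_26028 in leaves (0.108 and 0.0752 CPM) both levels lay below the floor of 3 counts, so no difference between responses was measured, and the fitted values (-4.87 and -5.06) depend on counts at the floor. That of PsbS was -7.81 without replicate 1 and -3.41 without replicate 2, and that of JMJ30 -6.59 without replicate 2 and -6.80 without control leaf 2. At least 1 of the 4 groups lay below 1 CPM for NPF7.3, the antiporter, ERF020, D1007_18268, D1007_33085, expansin A2, asparagine synthetase, HV58, the kinase, LOGL9, isocitrate lyase and the HV90 locus, so the size of these differences is uncertain. Leaves held 1.67 and 0.15 CPM for asparagine synthetase and 0 and 0.599 CPM for ERF020, and roots 0.664 and 0.223 CPM for HV58 and 0.267 and 0.455 CPM for LOGL9. Fitted values of genes with no count in a group depend on the prior count and are no bounds.

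Several differences moved by over 1.5-fold with libraries left out. At 40% purple acid phosphatase 27 moved to -4.76 without replicate 2 of every group, -2.85 without replicate 3 and -4.65 without control leaf 2. At 100%, leaving out replicate 1 gave -7.22 for NPF7.3, -8.86 for adenylylsulfate reductase, -7.15 for the HV90 locus, -9.08 for the kinase, -8.80 for ERF020, 6.13 for the antiporter, 2.35 for D1007_18268, 3.63 for asparagine synthetase, 8.67 for expansin A2 and 10.1 for LOGL9. Leaving out replicate 2 gave -9.89 for NPF7.3, -5.19 for the HV90 locus, -18.09 for HV58, -11.48 for the kinase, -3.70 for A-2d, 6.29 for asparagine synthetase, 11.37 for D1007_33085, 4.32 for expansin A2, 13.36 for LOGL9 and 18.62 for isocitrate lyase. Leaving out replicate 3 gave 1.01 for oligopeptide transporter 7, 1.30 for DUR3, 2.89 for asparagine synthetase, -6.43 for adenylylsulfate reductase, -15.86 for HV58, -1.80 for the heat shock locus and -10.80 for ERF020. It gave 7.17 for D1007_33085, 11.5 for expansin A2, 2.07 for LOGL9 and 16.33 for isocitrate lyase. Leaving out control leaf 2 alone gave -10 for NPF7.3, 10.28 for D1007_33085 and 4.05 for expansin A2.

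In every fit run, the call stayed for D1007_07770, D1007_16146, D1007_24918, D1007_25456, D1007_25844, D1007_27011, D1007_28888, D1007_29299, D1007_30290, D1007_31007, D1007_33860, D1007_40217 and D1007_52816. Of the 35 calls named at 100%, PsbS and JMJ30 included, 19 ended without replicate 1 of every group (adjusted p 0.065 to 0.26), 11 without replicate 2 (0.055 to 0.36), 16 without replicate 3 (0.053 to 1) and 3 without control leaf 2 alone (0.051 to 0.24). The count was 627, 1745 and 1398 genes without replicates 1, 2 and 3. For the whole count at 100%, 2 of 40 drawn splits, the real one included, called as many genes. The other called 4463 genes and exchanged the labels of all 3 leaf libraries of both groups while keeping those of the roots, so it tested the sum of both changes in place of their difference. Of the 39 without it, the real one called 3827 genes and the highest other 2805, which kept all leaf labels. As mixing labels adds spread, chance stays open.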

How the results depend on the processing

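Library size alone, voom with sample weights, the 2 corrected sets, the leave-one-out fits of the sets and the fits of other comparisons without control leaf 2 were chosen only after the results were seen. Counts are of genes called, with the number reported above given first, and unless stated otherwise the cause of a difference was not tested.

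In leaves, the 2 calls of 40% against the control became 6 without a filter, 0 with a replicate block, 1585 with DESeq2, 2123 with voom and sample weights, 13 with the 6 compared libraries alone and 1518 with all 18 libraries in 1 fit. The 4597 calls of 100% against the control became 7396 and the 3730 of 100% against 40% became 6700 with all 18 libraries, and the latter became 5697 with DESeq2. Leaving out 1 library gave 0 to 1035, 2388 to 4353 and 1501 to 3789 calls.

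In roots, the 67 calls of 40% against the control became 208 without a filter, 17 with a block, 1155 with DESeq2, 484 with voom, 35 with the 6 libraries alone and 1 with all 18. The 2240 calls of 100% against the control became 1335 at a minimum log2 change of 1, which removes genes by construction, 3834 with DESeq2, 4392 with voom and 501 with all 18 libraries. The 1005 calls of 100% against 40% became 667 at that minimum, 430 with a block, 2369 with DESeq2, 237 with the 6 libraries alone and 183 with all 18. Leaving out 1 library gave 0 to 151, 571 to 2086 and 209 to 872 calls. In simulated data DESeq2 recovered more of the changed genes than edgeR and made more false calls.

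The 456 genes at which the tissues differed at 40% became 211 with a block and 1827 with DESeq2, and 0 to 1348 with libraries left out. The 3827 at 100% became 627 to 3772 with libraries left out. The 13506 genes of leaf against root at 0% stayed within 10855 to 14285 over all alternatives.

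The gene sets that passed numbered 2, 5 and 2 in leaves (40% and 100% against the control, and 100% against 40%) and 2, 5 and 5 in roots. With at least 5 CPM they numbered 4 for 40% in leaves, 4 for 40% in roots, 8 for 100% in roots and 11 for 100% against 40% in roots. With an estimated correlation 0 passed in each of the 6 comparisons. With fry, 0 passed for 40% in either tissue in the directional test, and 27, 34, 34, 29, 35 and 33 in the test of change in either direction. Leaving out 1 library gave 1 to 4, 4 to 6 and 0 to 2 in leaves and 1 to 5, 4 to 8 and 6 to 8 in roots. Of the 21 passing sets, 20 passed with a block, 20 with at least 5 CPM, 11 in the directional fry test and 21 with the corrected sets.

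Of 202 results of named genes, 167 were called, of which 84 were called in every alternative and 83 were lost in at least 1. No called gene changed sign in any alternative run. Among the 35 uncalled results, 7 fits with 1 library left out changed the sign. The log2 change ranged from -0.74 to 0.01 for D1007_57662 at 40% in leaves, from -0.24 to 0.18 for it and from -0.18 to 0.44 for D1007_44398 at 40% in roots. For 100% against 40% in roots it ranged from -0.2 to 0.2 for D1007_38808 and from -0.13 to 0.62 for D1007_44398. Depth limits genes near the floor of 0.158 to 0.231 CPM, and in simulated leaf data 42.7% of genes changed 4-fold were recovered.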

Other observations

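The tests of scaling, of a swap, of depth and of shoot tissue, and the choice of the clock genes named here and of the set tests of the difference between tissues, were made only after the results were seen.

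Clock genes moved in both tissues at 100% against the control. LHY D1007_00729, a dawn gene of the clock, rose by 3.36 ± 0.35 in leaves (adjusted p = 0.00048) and by 2.60 ± 0.19 in roots (adjusted p = 0.00017). LNK1 D1007_24309, a partner of dawn clock factors, rose by 1.29 ± 0.21 in leaves and 2.26 ± 0.17 in roots. PRR95 D1007_25582, a later-phased clock repressor, fell by 2.20 (SE 0.20) in leaves and by 0.88 (SE 0.16) in roots, where the call (adjusted p = 0.012, alternatives 3.7e-05 to 0.056) was lost without control root 2 (0.056). GIGANTEA D1007_33900, an evening gene, was at 200 ± 74.9 against 194 ± 58.5 CPM in leaves (adjusted p = 0.53) and rose from 358 ± 54 to 761 ± 92.8 CPM in roots (adjusted p = 0.0039, alternatives 3.2e-14 to 0.061, the highest with all 18 libraries in 1 fit). At 40% LHY was not called by edgeR in leaves (adjusted p = 0.3) or roots (adjusted p = 0.12), but was by voom with sample weights in leaves (0.036) and roots (0.045) and by DESeq2 in roots (0.0099). The clock set without efflux carriers had 4 of 17 genes higher and 3 lower in leaves (5 and 3 adjusted over the list alone, set-adjusted p = 0.45) and 5 and 3 in roots (6 and 4 adjusted over the list alone, set-adjusted p = 0.248). In leaves its median was 0.3 and its mean -0.07.

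Other sets did not pass. In leaves at 100% WRKY factors had 18 of 59 genes higher and 3 lower (21 and 4 adjusted over the list alone, set-adjusted p = 0.0818), pathogenesis-related proteins 30 of 166 higher and 11 lower (the same adjusted over the list alone, set-adjusted p = 0.48) and aminotransferases 9 of 55 higher and 8 lower (11 and 9 adjusted over the list alone, set-adjusted p = 0.767; median -0.06, mean 0.06). In leaves at 40% senescence and proteolysis genes had 0 of 101 called by edgeR over all genes, and 2 higher and 20 lower adjusted over the list alone (set-adjusted p = 0.103). In roots at 100% pathogenesis-related proteins had 7 of 215 higher and 21 lower (12 and 29 adjusted over the list alone, set-adjusted p = 0.246) and histone and cell cycle genes 20 of 243 higher and 4 lower (18 and 4 adjusted over the list alone, set-adjusted p = 0.217).

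As sets, the difference between the root and leaf responses at 100% was negative for WRKY factors (59 genes tested in leaf and 81 in root, median -0.88, set-adjusted p = 0.01), peroxidases and glutathione S-transferases (100 and 175 tested, -0.48, set-adjusted p = 0.03) and chlorophyll synthesis (17 and 15 tested, -0.84, set-adjusted p = 0.038), with an adjusted p of 0.75 each with an estimated correlation. It was positive for ribosomal proteins (322 and 327 tested, 0.48, set-adjusted p = 0.01; adjusted p = 0.95 with an estimated correlation). At 40% it was negative for the Calvin cycle (36 and 21 tested, -0.25, set-adjusted p = 0.048; adjusted p = 0.89 with an estimated correlation). Genes tested in one tissue alone bring levels near the floor in the other.

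Clock and heat shock genes moved in both tissues at 100%, and a harvest at another hour or temperature is a candidate explanation. On clock genes set apart from those named above, dawn genes were higher and dusk genes lower in 18 of 22 pairs of a gene and a tissue (81.8%), while the dusk gene D1007_35872 was higher in both tissues and 2 dawn genes were lower in roots. Scaling between libraries as the whole cause is argued against, since it moves all genes alike. Library size alone shifted the median of all genes by -0.25 in leaves and 0.05 in roots, while the called clock and heat shock genes had a median absolute log2 change of at least 1.45 under 4 scalings. Scaling did change calls, from 47 heat shock genes higher and 10 lower in leaves to 39 and 20. The hour of harvest stays open, also for the other changes at 100%, because all libraries of a group may share it. The fertilizer itself stays open as an untested biological explanation.

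Control leaf 2 resembled the 40% leaves. A swap with a 40% leaf is argued against, since no 40% leaf correlated better with control leaves 1 and 3 than with its own group, the nearest difference being -0.055. A single wrong label stays open. Of 1029 genes used (1035 called without it), control leaf 2 lay nearer the 40% mean at 74.8%. The 40% leaves, each left out along with it, gave 99.4, 97.7 and 92.4%, but over fewer genes (345, 469 and 619). Its depth of 18.7 M counts lay within the range of the other leaves. No biological explanation was tested.

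The 3 cellulose synthases CESA4, CESA7 and CESA9 rose in roots at 40%. Green shoot tissue in the roots is argued against by a photosystem sum of 114 ± 2.63 CPM against 116 ± 12.1 in controls (ratio 0.982). Other shoot tissue was not tested. A single library as the whole cause is argued against, since the lowest log2 change with any of the 6 libraries left out was 2.67, although calls ended in 5 of those 6 fits. The adjusted p of CESA4, CESA9 and CESA7 was 0.053, 0.069 and 0.083 without control root 1, 0.21, 0.2 and 0.24 without control root 2, and 0.083, 0.1 and 0.083 without control root 3. That of CESA4 and CESA7 was 0.06 and 0.092 without 40% root 2, and that of CESA7 0.055 without 40% root 3. A larger share of cells with secondary walls cannot be told apart from a change within cells, since 15 of 15 other wall markers were higher, 3 of them called, with a median of 0.91. The fertilizer stays open as an untested biological explanation.

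Both comparisons with a tissue's control share it. Of 67 genes called in roots at 40%, 26 were higher and 24 lower at both rates and 1 moved oppositely, against 1.7 each for independent calls. With few calls, 10 simulations with shared controls and no change (0.1) cannot test this. Across non-independent genes, the 2 changes correlated at 0.6 in roots and 0.38 in leaves (0.5 from shared controls alone). Covariances were 0.42 and 0.608 (0.0868 and 0.219 from these).

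Exchanging labels among the 6 libraries of a comparison allows 10 splits, too few for a share under 0.05. In leaves the real split called 2 genes at 40%, 4597 at 100% and 3730 for 100% against 40%, and the highest other split 0 each time. In roots the real split called 67, 2240 and 1005 genes and the highest other 0, 0 and 2, and for leaf against root at 0% they called 13506 and 0. For sets the real splits passed 2, 5 and 2 in leaves and 2, 5 and 5 in roots, and the highest other 8, 9 and 4 in leaves and 4, 7 and 8 in roots. As many sets as in the real split passed in 9, 4 and 6 of 10 splits in leaves and 6, 5 and 3 of 10 in roots, the real one included. At 40% in leaves another split passed 8 sets where the real one passed 2, which points to a structure of the samples or to the preset correlation of 0.01, and no test told these apart.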
